A study of Homo sapiens with 40 samples.

How the data were processed

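ERα, FOXA1 and H3K27ac were measured by ChIP-seq in MCF-7 cells with Luc or PARP-1 knockdown, treated with vehicle or with 100 nM E2 for 40 min. The labels list 40 samples in 20 groups of 2 replicates, 12 groups of ChIP libraries and 8 of input libraries, the inputs in 2 sets. Groups were taken from the sample titles, because the treatment field of the PARP-1 knockdown ERα samples names the antibody target in place of the treatment. The labels call the replicates biological and give no culture or date for them, so some may share a culture.

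The deposited data used here were 24 peak lists, 12 in hg19 coordinates and a copy of each in hg38. Bowtie, bedtools and hg19 are named per the submitters' processing notes, with no version or role. The peak caller, the way the 2 replicates were combined, the way hg38 coordinates were made and any filter on the lists are not given in the sources used here. Each list gives for every peak, as deposited by the authors, a linear ratio (fold enrichment over the local background) and the −log10 p-value and −log10 q-value, with the summit position. Names and values were the same in both copies, and 0 to 11 peaks per list were missing from the hg38 copy. The number in a peak's name follows the order of p within a longer call set, and the lists hold between 9.84% and 82.8% of those numbers, so the deposited lists are filtered subsets. Lists set against each other were not cut alike. With E2 the ERα lists hold 17.2% of the numbers in Luc and 74.6% in PARP-1 knockdown. Of the FOXA1 E2 peaks 0.455% in Luc and 13.1% in PARP-1 knockdown had a q above 0.05. Fold was used to describe, rank or group peaks within their own list, and together with −log10 p to estimate tag densities, which were compared between lists and used to scale one list to another.

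The depth per library was not used here. For each list the fold and −log10 p of up to 3000 peaks were solved together for a tag pileup and a Poisson background, on the model that fold is pileup plus 1 over background plus 1, and 99.6% to 100% of the peaks tried were solved. The background value shared by the most peaks, divided by the shortest peak width taken as the fragment length, gave the tag density of the smaller of the ChIP and control libraries, to which the larger was scaled. Steps in the pileups and backgrounds gave the densities of both. These densities are estimates that rest on that model.

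Peaks of the hg38 copies were compared as sets. A peak was shared if it overlapped a peak of the other list by at least 1 bp. Shares carry 95% Wilson intervals and differences of shares 95% Newcombe intervals, and each share was set beside the mean of 1000 random placements of the peaks on their own chromosomes. With 1 list per condition there was no replicate test and no p-value between conditions. Genes were the 20037 protein-coding genes of the GRCh38.p14 RefSeq table, which gives each gene's span without strand, exons or introns. A gene counted as bound by ERα or FOXA1 if a summit lay in its span or within 50 kb of it, and as carrying H3K27ac if a peak lay within 1 kb of either end. Transcription start sites had been planned in place of spans and ends, and were replaced because the table has no strand. A planned comparison of estrogen response element sequences was left out, since no genome sequence was used here.

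The comparisons, their tests, the alternatives and 12 gene lists with 147 genes were fixed before the data were examined. The lists were estrogen-induced genes, estrogen-repressed genes, luminal epithelial identity genes, basal and mesenchymal markers, leukocyte markers, hepatocyte markers, neuronal markers, housekeeping genes, nuclear receptor coregulators, PARP family and ADP-ribosylation genes, cell cycle genes and immediate-early genes. A list's count was placed among 10000 random lists of the same size matched on an H3K27ac peak at a gene end in Luc knockdown with vehicle, as a description. Named sites were the 10 peaks of highest fold among the shared peaks and among those of either list alone, each with the nearest protein-coding gene within 50 kb, or called intergenic. From each gene list up to 4 members of highest fold and the members that differed between lists could be named, and TFF1, GREB1, PGR, MYC, CCND1, ESR1, FOXA1, GATA3 and PARP1 were always examined. Where fewer are named, they lead that order.

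The alternatives were peaks of −log10 q of 10 or more, a reciprocal overlap of 50%, lists of equal length by their own −log10 q, the hg19 lists, the ERα summit inside the other peak, differences within 10 classes of the list's own fold, windows of 20 and 100 kb, and a background of all protein-coding genes. The last was planned for ERα at the estrogen-induced genes in Luc knockdown with E2, and was extended to the other lists after the data were seen, when a background matched also on gene length was added. Peaks of −log10 p of 10 or more, with and without scaling to the lower tag density, were added then too for the ERα peaks shared between knockdowns with E2. On simulated data the overlap step found 200 of 200 planted overlaps among 6460 peaks of the Luc knockdown E2 ERα list, and the density step recovered the background and scaling of 4 of 4 simulated lists with 12204 peaks. Those lists were drawn from the model that the step solves, so they do not test the model. The shortest peak width as fragment length was not simulated. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.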

Results

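Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in MCF-7 cells, a luminal breast cancer cell line that carries estrogen receptor α (ERα) and grows in response to estrogen. Cells carried a knockdown of PARP-1, a nuclear enzyme that adds ADP-ribose to proteins, or a control knockdown against luciferase (Luc), a gene absent from human cells. After 3 days in medium stripped of steroids they received vehicle (ethanol) or 100 nM estradiol (E2), the main natural ligand of ERα, for 40 min. ERα, FOXA1, a pioneer transcription factor, and H3K27ac, the histone acetylation found at active enhancers and promoters, were each profiled in 4 conditions with 2 replicate libraries. The series has 24 ChIP libraries, 16 input libraries and 12 peak lists, 1 per factor, knockdown and treatment. Which inputs were used for each list is not given in the sources used here. The comparisons ask where sites differed between vehicle and E2, and between the knockdowns, since the series concerns PARP-1 in estrogen-dependent transcription.

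With vehicle, ERα had 62 peaks in Luc knockdown cells and 381 in PARP-1 knockdown cells. With E2 it had 6459 and 4611. FOXA1 had 54239 peaks with vehicle and 67675 with E2 in Luc knockdown, and 77260 and 63561 in PARP-1 knockdown. H3K27ac had 54982 and 57007 peaks in Luc knockdown, and 63236 and 50845 in PARP-1 knockdown. The tag density behind a list, estimated from its fold and p-values, was 5.32 tags per kb for each PARP-1 knockdown E2 list and 7.78 for each PARP-1 knockdown vehicle list. Both are densities of the control, to which the denser ChIP libraries of these lists were scaled down. The density behind the 6 Luc knockdown lists lay between 7.12 and 8.88. Each condition had 1 list, so no difference could be set against the spread between replicates, and the 95% intervals given here cover counting error over sites only.

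**Figure D1:**
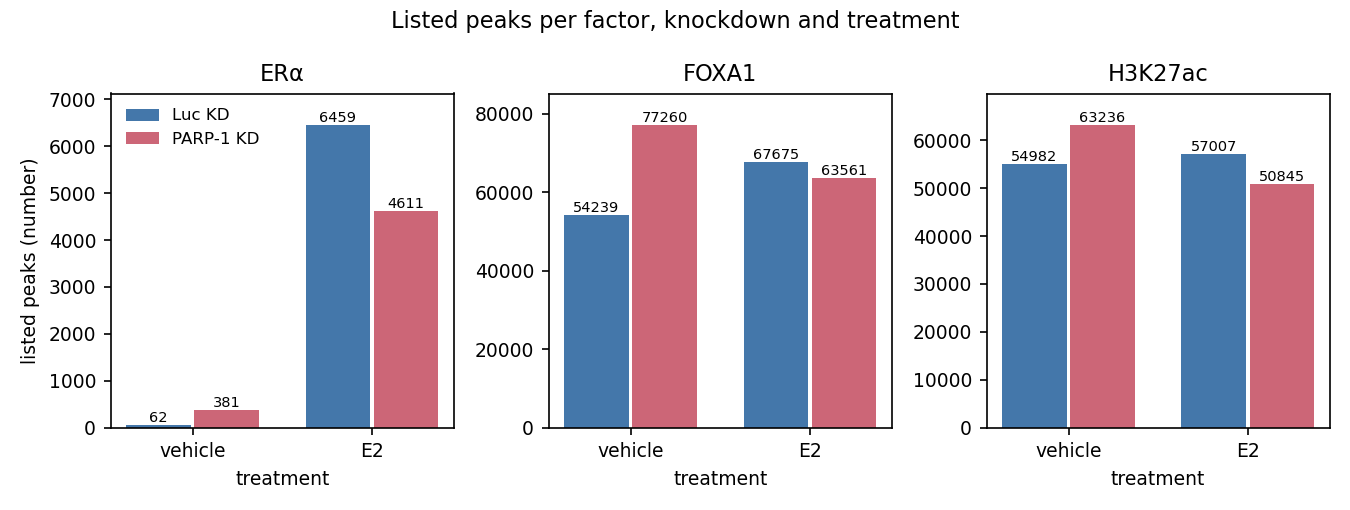
Bars give the number of listed peaks (vertical axis, each panel with its own scale from 0) for vehicle and E2, with Luc knockdown in blue and PARP-1 knockdown in red. ERα peaks number 62 and 381 with vehicle against 6459 and 4611 with E2, and the FOXA1 and H3K27ac lists are longest in PARP-1 knockdown with vehicle. At −log10 q of 10 or more, which is not drawn, the Luc knockdown E2 lists are the longest, with 31556 and 25023 peaks.

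In Luc knockdown cells with E2, ERα was listed near most of the estrogen-induced genes examined. Of 26 estrogen-induced genes, 24 had an ERα summit inside the gene or within 50 kb of it, against 2 with vehicle, ADCY9 and EGR3. The highest fold enrichments, which are the authors' values for each peak, were 47.1 at CTSD, a lysosomal protease, 42.1 at GREB1, an estrogen-induced growth regulator, 38.3 at IGFBP4, which binds insulin-like growth factors, and 37.5 at RARA, a retinoic acid receptor. CXCL12 and RAPGEFL1 had no peak. None of 10000 random gene lists, matched on H3K27ac at a gene end, had as many members with a peak, and the median random list had 8. Only 20 of the 6459 E2 peaks, or 0.310% (95% Wilson interval 0.201 to 0.478), overlapped a vehicle peak, against 0.00176% for randomly placed peaks. Their median fold in the E2 list was 22.0, against 6.47 for the other E2 peaks, and they included peaks in ATRNL1, TMEM229B, POC1B, PEBP4 and IL24. The strongest E2-only peak, of fold 92.1, lay in WWC1, a scaffold of the Hippo pathway, on chromosome 5 from 168316142 to 168316729 (hg38). Others of fold 54.8 to 77.1 lay in LOC124904102, ITPK1, TP63, GATA4, AFF3, CAMTA1 and ARHGEF10L, and between genes on chromosomes 21 and 10. Of the 42 vehicle peaks without an E2 partner the strongest, of fold 5.33, lay in SUZ12, a Polycomb subunit, followed by BRWD1 and HNRNPUL1. When the longer list was shortened to its 62 strongest peaks the share was 4.84%, and among peaks of −log10 q of at least 10 it was 0.105%.

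PARP-1 knockdown cells with E2 had a shorter ERα list that held nearly all of the strongest Luc knockdown sites. Of the 6459 Luc knockdown peaks, 3548, or 54.9% (53.7 to 56.1), overlapped a PARP-1 knockdown peak and are called kept here, against 0.0982% for random placement. The other 2911 are called lost. The 2 lists were not cut alike: by the numbers in the peak names, the Luc knockdown list holds 17.2% of its call set and the PARP-1 knockdown list 74.6%. All 646 peaks of the strongest 10% by fold were kept, and 7.12% of the weakest 10%. The strongest kept peaks were those in WWC1, LOC124904102, ITPK1, TP63, a p53 family member of basal epithelium, GATA4, AFF3, CAMTA1 and ARHGEF10L. The strongest lost peaks had folds of 12.1 to 15.7 and lay near TMEM92, CLDN14 and MAGEF1, in TMIGD3, in MGLL, a lipase, in ITPR1, a calcium channel, in EVL, LOC124901867 and TMPRSS3, and between genes on chromosome 5. Of the 4611 PARP-1 knockdown peaks, 76.8% (75.6 to 78.0) lay at a Luc knockdown peak. The strongest of the other 1070 had folds of 7.58 to 9.28 and lay in KIF16B, NEGR1, ARSG, RAPGEFL1 and PLPP3, near LRRC58, POFUT2 and TMEM130, and between genes on chromosomes 12 and 5. The tag density was 5.32 per kb behind the PARP-1 knockdown list and 7.27 behind the Luc knockdown list. The first is that of the control and the second that of the ChIP. The estimated ChIP density in PARP-1 knockdown was 8.84, so its ChIP was not the sparser one. Of the 3758 Luc knockdown peaks at −log10 p of 10 or more 80.9% overlapped a PARP-1 knockdown peak, and of the 2805 that stayed at that p when scaled to the lower density 90.3%, both settings chosen after the data were seen. The planned settings, a stricter q in both lists and lists of equal length, gave lower shares than these, listed below with the other alternatives.

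**Figure D2:**
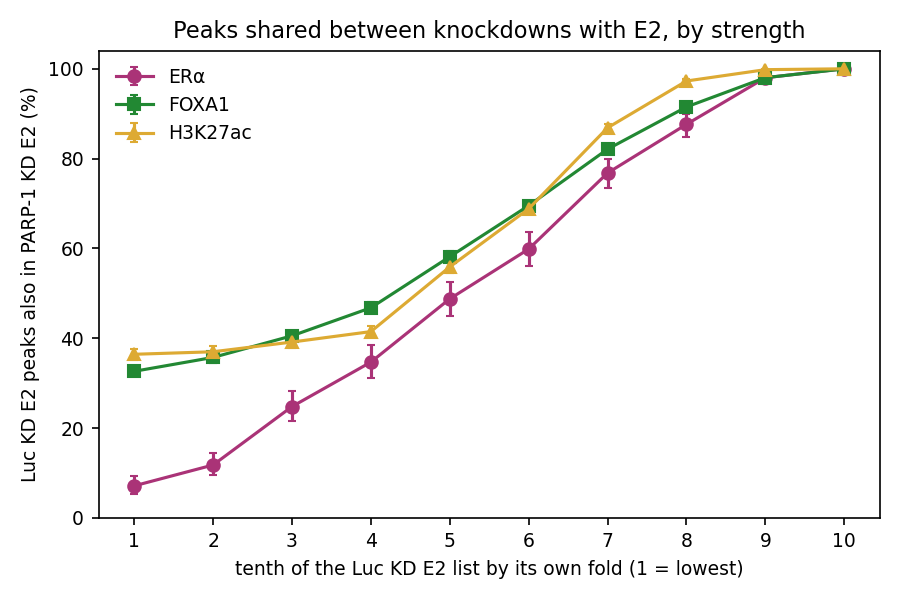
Points give the percentage of Luc knockdown E2 peaks that overlap a PARP-1 knockdown E2 peak (vertical axis), by class of the Luc knockdown list's own fold (horizontal axis, 10 classes of equal size, 1 the weakest), for ERα, FOXA1 and H3K27ac, with 95% Wilson intervals. In the weakest class ERα stands at 7.12%, FOXA1 at 32.6% and H3K27ac at 36.4%, and all 646 ERα peaks of the strongest class overlap.

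Most estrogen-induced genes had ERα peaks in both knockdowns with E2. This held for 22 of the 26, while MYC, a growth-promoting transcription factor, and STC2, a secreted glycoprotein, had one in Luc knockdown only, and RAPGEFL1 in PARP-1 knockdown only. None of 10000 random lists reached the 23 genes of PARP-1 knockdown. GREB1 had 10 ERα peaks in Luc and 7 in PARP-1 knockdown, the strongest inside its span on chromosome 2, from 11498533 to 11498950 in Luc and from 11498505 to 11498988 in PARP-1 knockdown. PGR, the progesterone receptor, had 4 and 2 peaks, CCND1, cyclin D1, had 2 and 2, and ESR1, which encodes ERα, had 2 and 2. The MYC peak, of fold 4.05, lay outside the gene on chromosome 8, from 127726625 to 127726859. FOXA1, GATA3 and PARP1 had no ERα peak within 50 kb in any of the 4 lists.

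At TFF1, which encodes a secreted trefoil peptide, ERα, FOXA1 and H3K27ac peaks were all more numerous with E2 than with vehicle in Luc knockdown. Within 50 kb of the gene on chromosome 21, ERα had 7 peaks in Luc and 5 in PARP-1 knockdown with E2, and none with vehicle. The strongest in Luc knockdown, of fold 32.2, lay in the neighbouring gene TMPRSS3 from 42376308 to 42376668, and another, of fold 26.7, covered an end of TFF1 from 42366335 to 42367032. Each of these overlapped a PARP-1 knockdown peak, while the TMPRSS3 peak from 42390771 to 42391049, of fold 12.5, did not. FOXA1 had 9 peaks with vehicle and 14 with E2 in Luc knockdown, and 10 and 10 in PARP-1 knockdown. H3K27ac had 7 peaks over 7.16 kb with vehicle and 22 over 36.2 kb with E2 in Luc knockdown. In PARP-1 knockdown it had 7 over 6.21 kb and 20 over 21.1 kb.

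**Figure D3:**
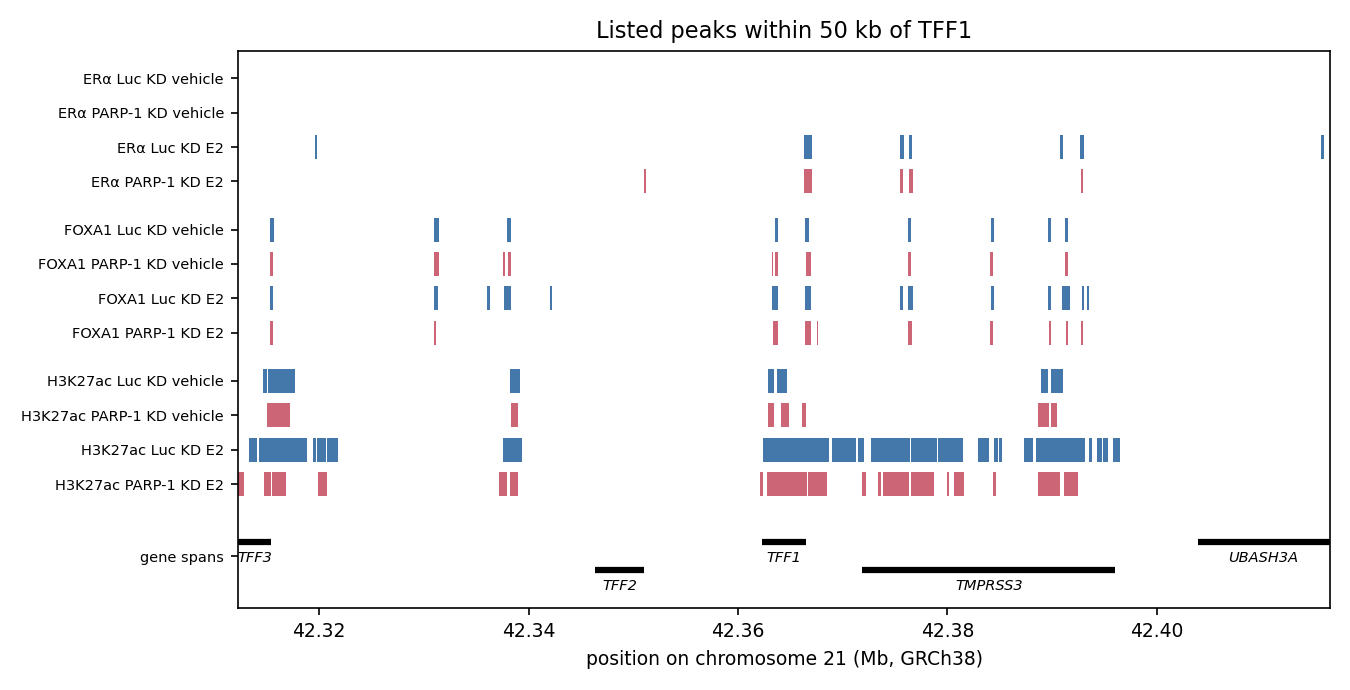
Boxes mark the listed peaks of the 12 lists within 50 kb of TFF1 (horizontal axis, position on chromosome 21 in Mb, hg38), with Luc knockdown in blue, PARP-1 knockdown in red and gene spans in black at the bottom. ERα has no peak here with vehicle and 7 and 5 with E2, and H3K27ac peaks cover 7.16 kb with vehicle and 36.2 kb with E2 in Luc knockdown.

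Kept ERα sites carried FOXA1 and H3K27ac more often than lost ones. In the Luc knockdown E2 lists, 63.2% of the 3548 kept peaks overlapped a FOXA1 peak, against 26.0% of the 2911 lost peaks, a difference of 37.2 percentage points (95% Newcombe interval 34.9 to 39.4). H3K27ac overlapped 77.5% of kept and 31.9% of lost peaks, a difference of 45.6 points (43.4 to 47.7). Of the ERα peaks of PARP-1 knockdown alone, 28.3% (25.7 to 31.1) had FOXA1 and 31.4% (28.7 to 34.2) H3K27ac in these lists. In the PARP-1 knockdown E2 lists they stood above the lost peaks, with FOXA1 at 29.8% (27.1 to 32.6) against 19.03% (17.6 to 20.5) and H3K27ac at 28.5% (25.9 to 31.3) against 19.6% (18.2 to 21.1), while kept peaks had 56.5% and 65.3%. Few ERα sites of either class lay within 1 kb of a gene end, 6.20% of kept and 4.47% of lost peaks. Kept peaks had a median fold of 9.28 and lost ones of 4.62, and within 10 classes of that fold the differences were 27.5 points for FOXA1 and 28.2 for H3K27ac. Among peaks of −log10 q of at least 10 they were 20.9 and 26.7 points, and with the ERα summit required inside the other peak 34.7 and 19.9. In the Luc knockdown vehicle lists the shares of kept and lost peaks were lower and lay fewer points apart. FOXA1 overlapped 22.97% of kept and 9.41% of lost peaks there, and H3K27ac 38.4% and 15.4%. ERα reads carried over into the FOXA1 libraries stay open as a source of part of the FOXA1 difference with E2.

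**Figure D4:**
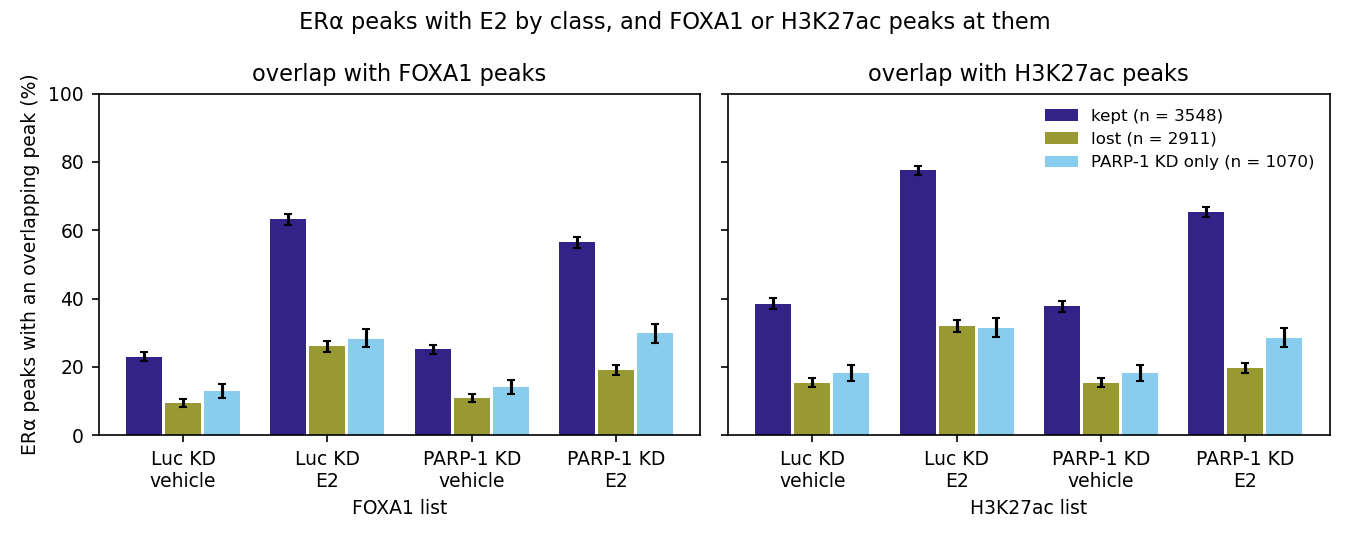
Bars give the percentage of ERα E2 peaks (vertical axis) that overlap a FOXA1 (left) or H3K27ac (right) peak of each condition (horizontal axis), with 95% Wilson intervals, for peaks kept in PARP-1 knockdown, lost in it, or listed in it alone. In the Luc knockdown E2 lists the kept peaks reach 63.2% and 77.5%, and the lost ones 26.0% and 31.9%.

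FOXA1 was listed at a minority of the later ERα sites with vehicle, and at more of them with E2. Of the 6459 ERα peaks of Luc knockdown cells with E2, 16.9% (16.0 to 17.8) overlapped a FOXA1 peak of the vehicle list, against 1.17% for random placement, and 46.4% (45.2 to 47.7) one of the E2 list. For H3K27ac the shares were 28.1% (26.97 to 29.2) and 56.9% (55.7 to 58.1). Of the 4611 ERα peaks of PARP-1 knockdown, 22.4% (21.3 to 23.7) overlapped FOXA1 with vehicle and 50.1% (48.7 to 51.6) with E2. H3K27ac overlapped 33.2% (31.8 to 34.6) and 56.0% (54.6 to 57.4) of them. ERα reads carried over into the FOXA1 libraries stay open as a source of the higher FOXA1 shares with E2.

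FOXA1 sites were mostly shared between vehicle and E2, and the E2-only sites lay at ERα more often than the shared ones. Among the 27607 E2-only peaks of Luc knockdown 6.84% overlapped an ERα peak, against 2.77% of the 40068 shared ones, a difference of 4.07 points (3.73 to 4.41). The strongest E2-only peaks, of fold 29.6 to 41.5, lay in SNX24 and MYO18A, near FST, which encodes the activin antagonist follistatin, near PRSS23, in MEGF9, MBP, WWC3, ATP8B1 and MAPKAP1, and between genes on chromosome 9. In PARP-1 knockdown SNX24 led the E2-only peaks as well, followed by THSD4, PDCD6IP and XYLT1. The strongest shared peak of Luc knockdown, of fold 120.3, lay in SAXO2, and the strongest of the 14398 vehicle-only peaks, of fold 14.8, in FTO. In Luc knockdown 59.2% (58.8 to 59.6) of the 67675 E2 peaks overlapped a vehicle peak, against 1.18% for random placement, and in PARP-1 knockdown 71.2% (70.9 to 71.6) of 63561. With lists of equal length the shares were 68.1% and 66.8%, so the order of the knockdowns turned. Within 10 classes of fold the difference in ERα overlap was 6.14 points. Carry-over of ERα reads into the FOXA1 libraries stays open for this difference too.

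H3K27ac at gene ends was mostly shared between vehicle and E2, and peaks of either treatment alone mostly lay elsewhere. Of the shared peaks of Luc knockdown, 37.2% (36.7 to 37.7) lay within 1 kb of a gene end, of the E2-only peaks 5.91% (5.59 to 6.24) and of the vehicle-only peaks 6.25% (5.92 to 6.60). E2-only peaks had a median fold of 4.47 and shared ones of 7.02 in the E2 list. These gene-end shares were not compared within classes of fold. The strongest of the 19816 E2-only peaks, of fold 21.8 to 25.7, lay near TLE3, a transcriptional corepressor, near MAX, the partner of MYC, near CPN2, in AFF3, GSE1, CAMTA1, THSD4 and ZNF385B, and between genes on chromosomes 11 and 21. In PARP-1 knockdown ZNF385B and RHOBTB1 led them. Shared peaks of Luc knockdown were led by SERINC2, MRPL48, MLST8 and BROX, and vehicle-only peaks, of fold up to 17.9, by a site between genes on chromosome 10 and by ARFGEF3 and SYDE2. In Luc knockdown 65.2% (64.8 to 65.6) of the 57007 E2 peaks overlapped a vehicle peak, against 3.76% for random placement, and in PARP-1 knockdown 75.1% (74.7 to 75.5) of 50845. ERα overlapped 10.3% of E2-only and 5.96% of shared peaks in Luc knockdown, a difference of 4.37 points (3.89 to 4.87). This was 8.62 points within 10 classes of fold, 19.3 among peaks of −log10 q of at least 10, and −1.31, the other way, with the ERα summit required inside the H3K27ac peak. With a reciprocal overlap of 50% the shares of E2 peaks at vehicle peaks were 39.3% in Luc and 41.2% in PARP-1 knockdown.

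More immediate-early and more estrogen-induced genes had a listed H3K27ac peak with E2 than with vehicle in both knockdowns, EGR3 being in both gene lists. All 12 immediate-early genes had one within 1 kb of a gene end with E2, against 10 with vehicle, EGR3 and ATF3, both inducible transcription factors, being the additions. As many were found in 0.16% of random lists in Luc and in 0.03% in PARP-1 knockdown. Of the 26 estrogen-induced genes 24 had such a peak with E2 and 22 with vehicle in each knockdown, KRT13, a keratin, and EGR3 being the additions, and 0.46% and 0.06% of random lists reached 24. With random lists matched also on gene length, a matching chosen after the data were seen, the shares for the immediate-early genes were 0.06% and 0.02%, and no list reached the 24 estrogen-induced genes in PARP-1 knockdown. Drawn from all protein-coding genes, a background also chosen for these lists after the data were seen, 0.25% and 0.13% of lists had as many immediate-early genes, and 0.02% in Luc and none in PARP-1 knockdown reached the 24 estrogen-induced genes, but with vehicle only 0.98% and 0.94% of such lists reached the 22, and 9.87% and 10.01% the 10 immediate-early genes. All 16 luminal epithelial identity genes, 15 cell cycle genes, 12 nuclear receptor coregulators and 10 housekeeping genes had one in each of the 4 lists. So did 11 of 12 PARP family and ADP-ribosylation genes, PARP1 among them, and 6 of 7 estrogen-repressed genes. Peak lists hold no expression values, so the depth of the PARP-1 knockdown was not measured here.

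FOXA1 sites of Luc knockdown that were missing from PARP-1 knockdown were mostly weak peaks. With E2, 32.6% of the weakest 10% overlapped a PARP-1 knockdown peak, and all but 3 peaks of the strongest 10%. The strongest Luc-only peaks with E2 had folds of 15.1 to 20.1 and lay near ABCC5, a transporter, near PXYLP1 and HHIP, in GALNT17, KIAA1958, NCKAP5 and TP73, a relative of p53, and between genes on chromosomes 10, 12 and 8. Those of PARP-1 knockdown alone, of fold up to 13.3, lay near TIA1 and TFDP3 and in SPOCK1, LUZP2, NOS1AP and ECHDC1. With vehicle, ZSCAN18, HCAR2 and EIF4EBP1 led the Luc-only peaks, of fold up to 12.0, and SDC4 led the 34171 PARP-only peaks, at fold 15.2. GATA3, a luminal transcription factor, and the FOXA1 gene had FOXA1 peaks within 50 kb in all 4 lists. With vehicle 78.3% (77.9 to 78.6) of the 54239 Luc knockdown peaks overlapped a PARP-1 knockdown peak, and with E2 65.5% (65.1 to 65.8) of 67675, against 1.54% and 1.20% for random placement.

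H3K27ac peaks listed with E2 in 1 knockdown alone lay at gene ends less often than shared ones. Of the 19232 peaks of Luc knockdown alone on chromosomes of the gene table, 9.83% (9.41 to 10.3) lay within 1 kb of a gene end, of those of PARP-1 knockdown alone 6.74% (6.18 to 7.34), and of the shared peaks 34.8% (34.3 to 35.2). Luc-only peaks were also weaker, with a median fold of 4.22 against 7.36 for shared ones. The gene-end shares were not compared within classes of fold, so strength was not separated from position. The strongest Luc-only peaks, of fold 11.5 to 16.9, lay near METRNL, POLDIP3 and PPP1R16A, in MAPRE3, in SNAI1, a transcription factor of epithelial-mesenchymal transition, in LOC124901227, ACSL4 and OSBPL5, and between genes on chromosome 12. ADAMTS6 led the 7170 peaks of PARP-1 knockdown alone, at fold 9.65. Of 12 basal and mesenchymal markers 7 had H3K27ac at a gene end with E2 in Luc knockdown and 5 in PARP-1 knockdown, VIM, which encodes vimentin, and FN1, fibronectin, making the difference, and with vehicle 8 and 7, with CAV1 in Luc knockdown only. As few as with E2 were found in 22.8% and 1.46% of random lists, and in 54.0% and 19.4% of those drawn from all protein-coding genes, a background chosen here after the data were seen. These markers are 1 of 12 gene lists, and the shares were not corrected for that number. VIM and FN1 had such a peak with vehicle in PARP-1 knockdown too. They were missing only with E2 there, in the H3K27ac list of the lowest tag density, 5.32 per kb. With vehicle, LOC105369669, RGS16 and CENPF led the Luc-only peaks, at fold up to 9.54, and TFB1M the PARP-only peaks, at fold 11.0. With vehicle 79.8% (79.5 to 80.2) of the 54982 Luc knockdown peaks overlapped a PARP-1 knockdown peak, and with E2 66.3% (65.9 to 66.6) of 57007, against 3.85% and 3.07% for random placement.

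Luminal epithelial identity genes also had ERα peaks with E2 more often than random lists, and no leukocyte marker had one. In Luc and PARP-1 knockdown 14 and 12 of the 16 luminal genes had a peak within 50 kb, MUC1 and AGR2 in Luc knockdown only. XBP1 (fold 27.4), the keratins KRT8 and KRT18 (24.5) and the adhesion gene CDH1 (15.8) were the strongest in Luc knockdown. None of 10000 random lists had 14, and 0.01% had 12. Nuclear receptor coregulators gave 7 and 4 of 12, NCOR1, CREBBP and CARM1 in Luc knockdown only, with 4.41% and 31.9% of random lists as high. Cell cycle genes gave 7 and 5 of 15, CCNA2 and MCM5 in Luc knockdown only, with 14.8% and 27.7% as high. Immediate-early genes gave 6 and 3 of 12, with 11.1% and 53.0% as high, FOSL2, ATF3 and MYC in Luc knockdown only, and IER3 had their strongest peak, of fold 40.2. Housekeeping genes gave 4 and 2 of 10, with GAPDH, HPRT1 and RPLP0 in Luc and UBC in PARP-1 knockdown only. Basal and mesenchymal markers gave 4 and 4 of 12, led by TP63, PARP family and ADP-ribosylation genes 3 and 3 of 12, led by NMNAT1, an enzyme of NAD synthesis, and estrogen-repressed genes 1 and 1 of 7, NEDD9. Hepatocyte markers gave 3 and 2 of 10, TF in Luc knockdown only, and neuronal markers 3 and 2 of 10, MAP2 in Luc knockdown only. For the 6 lists from housekeeping genes to neuronal markers between 24.8% and 91.55% of random lists had as many. Of the 10 leukocyte markers 0 had a peak in either knockdown, and 6.23% and 13.0% of random lists had as few. With random lists matched also on gene length, a matching chosen after the data were seen, 15.2% and 57.1% had as many coregulators, 7.24% and 16.3% as many cell cycle genes, 5.45% in Luc knockdown as many immediate-early genes, and none in PARP-1 knockdown as many luminal genes. Drawn from all protein-coding genes, a background also chosen for these lists after the data were seen, 2.22% in Luc knockdown had as many coregulators, 8.99% as many cell cycle genes and 4.04% as few leukocyte markers, and none in PARP-1 knockdown had as many luminal genes.

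With vehicle, the ERα peaks of the 2 knockdowns were few and partly shared. Shared peaks lay in CTPS2, the strongest at fold 8.09, ATRNL1, POC1B, IL24, HNRNPUL1, PEBP4 and IPPK, and near CYP2A7 and CDH17. The strongest of the 364 peaks of PARP-1 knockdown alone lay in RARA, near A4GALT and in SIAH2, an E3 ubiquitin ligase, at folds of 6.50, 5.91 and 5.55. Of the 62 Luc knockdown peaks 27.4% (17.9 to 39.6) overlapped a PARP-1 knockdown peak, against 0.00806% for random placement. In PARP-1 knockdown 0.586% (0.403 to 0.851) of the 4611 E2 peaks overlapped a vehicle peak, the strongest in POC1B, TMEM229B, IL24 and RARA, and the strongest E2-only peak, of fold 53.2, was the one in GREB1. Of the vehicle peaks 66.1% in Luc and 89.0% in PARP-1 knockdown had a q above 0.05, and among those of −log10 q of at least 10 all 3 of Luc knockdown were shared. The share of PARP-1 knockdown E2 peaks at vehicle peaks was 4.72% with lists of equal length and 0.317% at that stricter q.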

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

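The tests in this part were written before their results were seen. The number of FOXA1 and H3K27ac peaks moved in opposite directions with E2 in the 2 knockdowns, and that difference was not tested, since each condition has 1 list. FOXA1 peaks with E2 over those with vehicle gave a ratio of 1.25 in Luc and 0.823 in PARP-1 knockdown. For H3K27ac the ratios were 1.04 and 0.804.

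The shorter E2 lists in PARP-1 knockdown may come from the tag density, 5.32 per kb with E2 against 7.78 with vehicle: scaled to the E2 density, the vehicle lists kept 22899 of 32764 FOXA1 peaks at −log10 p of 10 or more, against 25806 with E2, and 20666 of 27683 H3K27ac peaks, against 20962. The rule asked only that the scaled number not exceed the E2 number by more than 2 SDs. For H3K27ac the difference was −296 (SD 204, counting error only). For FOXA1 it was −2907 (SD 221), so density alone would take away more FOXA1 peaks than were missing. The unstated filter alone was argued against, since by the order in the peak names the call sets before filtering reached that p at rank 25852 with E2 and 32840 with vehicle for FOXA1, and at 20968 and 27688 for H3K27ac. An effect of PARP-1 knockdown on the response to E2 stays open and was not tested, because no replicate lists were used here.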

How the results depend on the processing

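All settings in this part were planned, except, for the random gene lists, the background matched on gene length and, beyond ERα at the estrogen-induced genes in Luc knockdown with E2, that of all protein-coding genes, and, for the ERα peaks shared between knockdowns with E2, those at −log10 p of 10 or more with and without scaling, which were chosen after the data were seen. No paired analysis was possible because each condition has 1 list, so leaving out a replicate was not possible either. The comparison of estrogen response elements and its alternatives (at most 1 mismatch, a wider window) were not run. With the hg19 lists 17 of 17 results stayed within their intervals, and windows of 20 and 100 kb gave 22 and 24 estrogen-induced genes.

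Shares are given in the order E2 at vehicle in Luc, the same in PARP-1 knockdown, Luc at PARP-1 knockdown with vehicle, the same with E2. At −log10 q of 10 or more they were 0.105%, 0.317%, 100% (of 3 peaks) and 53.2% for ERα, 64.1%, 83.4%, 78.9% and 57.1% for FOXA1, and 74.0%, 86.6%, 86.8% and 64.6% for H3K27ac. Kept minus lost was then 20.9 points for FOXA1 and 26.7 for H3K27ac, E2-only minus shared 5.39 and 19.3, ERα peaks with FOXA1 at vehicle 15.6%, and estrogen-induced genes 21. Lists of equal length gave 4.84%, 4.72% and, last, 72.5% for ERα, with the share at vehicle as before, 68.1%, 66.8%, 69.9% and 68.2% for FOXA1, and 66.3%, 71.4%, 76.1% and 71.1% for H3K27ac. A reciprocal overlap of 50% gave 56.0%, 67.6%, 73.0% and 61.6% for FOXA1 and 39.3%, 41.2%, 57.1% and 44.8% for H3K27ac, with ERα within its intervals.

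With the ERα summit inside the other peak, kept minus lost was 34.7 and 19.9 points, E2-only minus shared 3.53 for FOXA1 and, turned in sign, −1.31 for H3K27ac, and ERα peaks with FOXA1 at vehicle 13.4%. Within 10 classes of fold the differences were 27.5, 28.2, 6.14 and 8.62 points. Beyond the smaller or narrower lists that these settings make, the cause was not tested.

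At −log10 q of 10 or more ERα kept 3 of 62, 2847 of 6459, 5 of 381 and 1578 of 4611 peaks (Luc vehicle, Luc E2, PARP-1 vehicle, PARP-1 E2), FOXA1 23965 of 54239, 31556 of 67675, 25014 of 77260 and 19416 of 63561, and H3K27ac 22555 of 54982, 25023 of 57007, 22970 of 63236 and 17302 of 50845. The longest FOXA1 and H3K27ac lists were then those of Luc knockdown with E2, no longer those of PARP-1 knockdown with vehicle. Of the 3758 ERα peaks of Luc knockdown with E2 at −log10 p of 10 or more 80.9% overlapped a PARP-1 knockdown peak, and of the 2805 that stayed there when scaled to the PARP-1 knockdown density 90.3%, against 54.9% of all. How much of this comes from depth and how much from keeping the stronger peaks was not tested. With 1 list per condition no setting shows the spread between replicates.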

Other observations

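The description of the strongest E2-only peaks, the tests of weak sites and of ERα reads in the FOXA1 libraries and the shares of peaks found before and after scaling were chosen only after the results were seen. In the strongest 10% of the FOXA1 E2 list of Luc knockdown 119 peaks were E2-only, among them those in SNX24 and MYO18A, and 94 of the 119, or 79.0% (95% Wilson interval 70.8 to 85.3), lay at an ERα peak, against 9.91% (9.22 to 10.7) of the 6649 shared ones. In PARP-1 knockdown it was 46 of 59, or 78.0% (65.9 to 86.6), against 8.43%. For H3K27ac it was 36 of 39 in Luc knockdown, or 92.3% (79.7 to 97.3), against 13.7%, and 24 of 28 in PARP-1 knockdown, or 85.7% (68.5 to 94.3), against 13.0%. FOXA1 peaks within 50 kb of PGR numbered 3 with vehicle and 10 with E2 in Luc knockdown, and 8 and 11 in PARP-1 knockdown.

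With vehicle, ERα peaks near estrogen-induced genes were listed for ADCY9 and EGR3 in both knockdowns and for RARA, SIAH2 and MYC in PARP-1 knockdown alone. The 5 of 26 genes in PARP-1 knockdown were matched by none of 10000 random lists, by 0.01% when these were drawn from all protein-coding genes, a background chosen here after the data were seen, and the 2 in Luc knockdown by 0.52%. Most peaks of these vehicle lists were weak, with a q above 0.05 for 66.1% in Luc and 89.0% in PARP-1 knockdown. The lists were not cut alike either, holding 29.8% and 9.84% of the numbers in the peak names. The estimated ChIP tag density was 16.1 per kb for the Luc and 8.26 for the PARP-1 knockdown vehicle list of ERα, from only 62 and 381 peaks. H3K27ac at a gene end of the hepatocyte marker APOA1 was listed with E2 and not with vehicle in both knockdowns, and at TP63 with vehicle and not with E2.

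ERα peaks with E2 were fewer in PARP-1 than in Luc knockdown, and the unstated filter as the cause was argued against, since the call sets before filtering reached −log10 p of 10 at rank 2309 in PARP-1 and 3812 in Luc knockdown. Tag density cannot be told apart from other causes. Scaled to the PARP-1 knockdown density, 2805 of 3758 Luc knockdown peaks (3008 under the other solution of the model) stayed at that p, against 2297 in PARP-1 knockdown. The excess of 508 is beyond 2 SDs of the difference (SD 71.4), which the rule written beforehand counts against density. Density is left open all the same, since that SD covers counting error only and 1 list per condition gives no spread between libraries. Of the 2805 peaks 273, or 9.73%, had no PARP-1 knockdown peak, against 719, or 19.1%, of the 3758 before scaling, and scaling also leaves the stronger peaks. Weak sites near the listing threshold stay open: 1.01% of peaks were lost in the 2 strongest of 10 classes of fold and 90.6% in the 2 weakest, but 0.157% and 49.8% of the Luc knockdown FOXA1 peaks were missing in the same way with vehicle, where the PARP-1 knockdown list is 1.42 times as long, so this course decides nothing. A weaker immunoprecipitation in 1 or more libraries and an effect of PARP-1 knockdown on ERα binding both stay open, and neither was tested.

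E2-only FOXA1 and H3K27ac peaks lay at ERα sites more often than shared ones. In Luc knockdown the tag density was lower with E2 than with vehicle for FOXA1 (7.12 against 7.76 per kb) and higher for H3K27ac (8.88 against 7.87), and a higher density of the E2 list was argued against, since in PARP-1 knockdown, where the E2 density is the lower one for both, the differences were 4.51 points (4.12 to 4.91) for FOXA1 and 4.67 (4.13 to 5.24) for H3K27ac. ERα reads carried over into the FOXA1 libraries stay open. Of the strongest 10% of ERα peaks 79.9% (76.6 to 82.8) had a FOXA1 peak, below the cut set for carry-over after the results were seen. How many strong sites carry-over must mark was not measured, so that cut decides nothing. The median summit distance of 59 bp, with 43.6% within 50 bp, is near what carry-over gives. For H3K27ac, which 97.4% had, the median summit distance of 427 bp argued against carry-over as the main signal of these peaks. Carry-over that only adds to a broad peak was not excluded, since these peaks had a median width of 1107 bp. Nor does the 97.4% speak against it. The difference in ERα overlap for H3K27ac in Luc knockdown was −1.31 points with the ERα summit required inside the peak, so that part depends on how overlap is defined. That FOXA1 and H3K27ac are gained where ERα binds after E2 remains a hypothesis, found and tested on the same data.

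The estimated control tag density was the same for the 3 factors within each condition, 7.87 per kb for Luc vehicle, 9.32 for Luc E2, 7.78 for PARP-1 vehicle and 5.32 for PARP-1 E2, differing by at most 0.0377%, although the labels list 2 input sets, of which 1 names FOXA1 and H3K27ac.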
